A study of Mus musculus with 12 samples.

How the data were processed

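RNA of mouse primary hepatic stellate cells was sequenced in 12 libraries, made with a stranded poly(A) kit per the labels' protocols. Cells had been isolated by density gradient centrifugation. The groups were quiescent (QS), activated (ACT), Hk2-deleted (KO) and Hk2-deleted with lactate (LAC), each with 3 libraries, and group and replicate number were read from the sample titles.

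The deposited table holds the authors' read counts normalized to library size (CPM) for 12081 genes and has a column per library. It was recorded as a signal because the column totals of the deposited values run from 959233 to 1047042, partly above what plain CPM can sum to, so each library carries a further scaling factor. Per the submitters' processing notes, FastQC 0.11.8, cutadapt 1.18, kallisto 0.44.0 and edgeR 3.8 were used with the mouse build mm10, without a stated role or order. Each gene has at least 1 CPM in at least 3 libraries, so a filter on low values had been applied before deposit. The normalization sets levels relative to the bulk of genes and cannot show a change in total RNA per cell. Because transcript counts were estimated, values that should be whole reads were mostly not: within 0.01 of a whole read lay 19.7% to 25.7% of the positive values of a library. Reads could therefore not be recovered and no count test was run. The value of a single read was nevertheless visible in low values shared by several genes, and gave the depth in the report, from 4.35 to 14.00 M (megareads) estimated in the listed genes. A level of 3 reads corresponds to 0.212 CPM in the deepest library and to 0.720 CPM in the shallowest. In genes of at least 200 CPM the median coefficient of variation was 3.38% in QS, 2.04% in ACT, 4.16% in KO and 2.42% in LAC, where counting error alone gives 2.39%, 1.50%, 1.97% and 1.76%. Libraries of a group differed by more than sampling noise, with a chi-square per gene of 2.25 to 4.61, so all were kept as separate. Genes with near-identical copies, such as the Mup, Serpina1 and Ifit families, share reads and their single values are uncertain.

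The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with 4 group means fitted to all 12 libraries, so that the groups share their estimate of the spread on 8 residual degrees of freedom, and with empirical Bayes moderation along the intensity trend. The filter of at least 1 CPM in at least 3 libraries removed no gene. P-values were adjusted by Benjamini-Hochberg within each comparison and a gene was called at an adjusted p under 0.05. The comparisons were ACT vs QS, KO vs ACT, LAC vs KO and LAC vs ACT. The test of Hk2 was repeated as an exact two-sided permutation test per pair of groups. Levels are means and SDs of CPM.

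Before the data were examined, 29 gene lists were fixed, with Hk2 left out of each: fibrillar matrix and crosslinking, contractile myofibroblast, TGF-beta responsive, matrix turnover, quiescent stellate, glycolysis, lactate transport and metabolism, histone acyltransferases and deacylases, pentose phosphate and hexosamine, tricarboxylic acid cycle, oxidative phosphorylation, cell cycle, p53 targets, integrated stress response, unfolded protein response, hypoxia targets, sterol synthesis, fatty acid synthesis and storage, interferon response, inflammatory chemokines and cytokines, growth factor receptors and ligands, immediate early and dissociation, hepatocyte, Kupffer cell and macrophage, endothelial, lymphocyte and neutrophil, cholangiocyte and mesothelial, and portal fibroblast and vascular smooth muscle markers, and mitochondrially encoded genes. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 116 tests, and again with an estimated correlation. Of 63 list tests called with the preset correlation, 33 were also called with the estimated one and 30 were not. Limma's fry, which asks only whether the genes of a list move in a common direction, called 105 of the 116 tests. The genes named for a comparison were the 10 largest rises and 10 largest falls among genes called, with at least 5 CPM in the higher group and no overlap between the groups, without predicted genes, then up to 4 called members per list with the largest change, and 14 genes fixed by name. Gene coordinates came from the GENCODE M21 annotation of the same build, in which 11887 symbols matched a single gene.

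Both relations between comparisons share libraries (ACT in the first, KO in the second). For them, the correlation and covariance of fold changes were set beside 100 simulations of groups without effect and beside fold changes with the shared libraries split. Alternatives were other pseudocounts (0.1, 0.5, 5), a higher filter (5 CPM), other scalings (an equal total per library, quantiles, medians), the replicate number as a block, fewer groups in the fit, other moderation, weights per library, other thresholds and leaving out each library. An alternative without marker genes of other cells and mitochondrially encoded genes and a test against a 1.2-fold change were added after the data were seen. Reads were also simulated at the real depths, with 200 genes changed among 12081. All libraries had the means of the comparison's second group, apart from the changed genes, and a small assumed spread equal for all genes. Changed genes were drawn above a minimum level, so the rates do not cover genes of low level. The tests recovered 37.3% to 41.8% of genes changed 1.2-fold over the 4 comparisons. They recovered 91.0% to 92.5% of those changed 1.5-fold and 98.5% to 100.0% of those changed 2-fold. Unchanged genes called were 8 of 162 calls in ACT vs QS (4.9%), 0 of 154 in KO vs ACT, 2 of 155 in LAC vs KO and 1 of 153 in LAC vs ACT. Of the lists without simulated change, 1 was called in LAC vs KO and 1 in LAC vs ACT. Python with NumPy, pandas, SciPy and Matplotlib read the table and drew the plots.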

Results

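RNA sequencing was performed on primary hepatic stellate cells, the vitamin A-storing pericytes of the liver that turn into collagen-producing myofibroblasts when activated. The cells came from mice in which both copies of Hk2, the gene of the glycolytic enzyme hexokinase 2, carry sites that Cre recombinase cuts. There were 4 groups of 3 libraries. Freshly isolated cells served as quiescent cells (QS). Activated cells were kept in culture for 6 days after transduction with an adenovirus that expresses a green fluorescent protein (ACT). Hk2-deleted cells received a virus that expresses Cre fused to that protein (KO), and a further group of Hk2-deleted cells was given 10 mM lactate for 24 h (LAC). The study addressed whether hexokinase 2 is needed for the gene expression of activated stellate cells and whether lactate, a product of glycolysis, replaces it. Expression was listed for 12081 genes as read counts normalized to library size (CPM). The estimated reads behind the listed genes, in M (megareads), ranged from 4.35 to 10.14 in QS, from 11.41 to 14.00 in ACT, from 5.85 to 11.64 in KO and from 8.67 to 11.05 in LAC. Levels are given as mean ± SD of the 3 libraries of a group, and log2 fold changes are on the log2(CPM + 1) scale, which understates the change of genes with low values. The groups were far apart and the libraries within a group close together: the first principal component held 61.5% of the variance and the second 28.1%, with LAC between ACT and KO on the second. No label says that the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

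Hk2 (mm10, chromosome 6, 82725025 to 82774454, minus strand) was lowest in the libraries that received Cre. Its level was 71.2 ± 3.88 CPM in QS, 181 ± 0.828 CPM in ACT, 12.1 ± 1.48 CPM in KO and 19.3 ± 0.575 CPM in LAC. KO thus held 6.7% of the ACT level, and LAC 10.7%. Every KO and LAC library lay below every QS and ACT library, from 10.7 to 19.7 CPM against 66.7 to 182 CPM. The log2 fold change was 1.34 for ACT against QS (SE 0.078, limma adjusted p = 1.23e-09), -3.80 for KO against ACT (adjusted p = 2.25e-14) and 0.64 for LAC against KO (adjusted p = 1.66e-05). A two-sided exact permutation test of each pair of groups gave p = 0.10, the smallest that 3 against 3 libraries can give. The labels do not say which exons are removed, so transcripts of the deleted allele may be among those counted. Hk1, which encodes another hexokinase, rose from 136 ± 2.47 CPM in ACT to 209 ± 11.2 CPM in KO (log2 fold change 0.61, adjusted p = 6.14e-08). Hk3, a hexokinase gene of myeloid cells, fell from 131 ± 4.82 to 2.58 ± 1.17 CPM (-5.25, adjusted p = 2.28e-12).

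**Figure D1:**
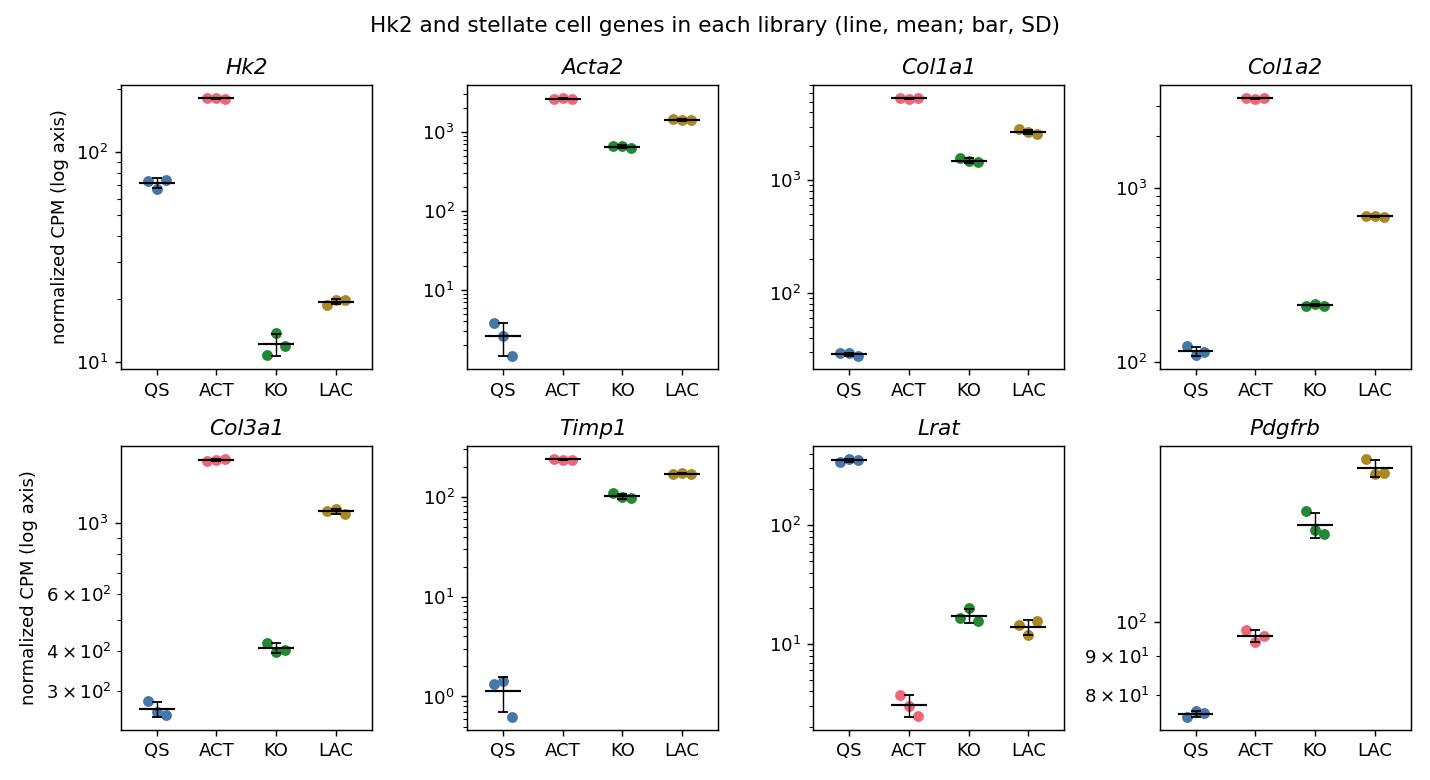
Normalized CPM (vertical log axis) of Hk2 and 7 stellate cell genes in the 12 libraries by group (horizontal axis). Points are libraries, lines are group means and bars are SDs. Acta2, Col1a1, Col1a2, Col3a1 and Timp1 lie highest in ACT, lower in KO and between both in LAC, as in Acta2 with 2656, 653 and 1434 CPM.

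Activated cells were compared with quiescent cells to describe what 6 days of culture did. Genes of contraction and matrix rose steeply. Acta2, which encodes the smooth muscle actin used as the marker of myofibroblasts, went from 2.64 ± 1.2 CPM in QS to 2656 ± 48.0 CPM in ACT (log2 fold change 9.56, SE 0.159, adjusted p = 1.24e-15). Col1a1, a chain of type I collagen, went from 28.6 ± 0.925 to 5341 ± 51.3 CPM, Col1a2 from 116 ± 7.22 to 3305 ± 18.6 CPM and Col3a1 from 263 ± 13.5 to 1572 ± 13.2 CPM. All 24 measured genes of the contractile list rose, with a median log2 fold change of 2.02 (camera adjusted p = 1.56e-12). They included Cnn1 (7.15), Tagln (6.65) and Actg2, which was listed at 0 in all 3 QS libraries and at 73.4 ± 3.14 CPM in ACT. Among 33 fibrillar matrix and crosslinking genes 28 rose and 4 fell (median 2.58, camera adjusted p = 7.10e-10), with Col12a1 (8.28), the crosslinking enzyme Lox (8.13) and Tnc (5.92) among the largest changes. Of 20 matrix turnover genes 17 rose and 2 fell (median 1.72, camera adjusted p = 1.68e-05), led by Timp1, an inhibitor of matrix proteases, at 237 ± 4.27 CPM against 1.14 ± 0.444 CPM in QS. Of 24 TGF-beta responsive genes 15 rose and 6 fell (camera adjusted p = 0.00405, adjusted p = 0.0591 with an estimated correlation), among them Ltbp2 (8.62), Tgfb3 (4.90) and Inhba (4.11). Quiescence genes went the other way. Of 34 quiescent stellate genes 30 fell and 4 rose (median -3.31, camera adjusted p = 1.89e-10), including Lrat, which esterifies retinol for storage, from 352 ± 11.4 to 3.09 ± 0.637 CPM, Colec11 (-6.56) and Colec10 (-8.75). Adjusted over the list alone, the members called in these 5 lists numbered the same as over all genes tested.

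Proliferation genes rose and interferon genes fell with culture. Of 38 cell cycle genes 36 rose and none fell (median 2.59, camera adjusted p = 6.55e-13), such as Rrm2 (4.01), Ccnb1 (3.74) and Top2a (3.53). All 29 interferon response genes fell (median -4.45, camera adjusted p = 2.72e-15). Rsad2, an antiviral interferon-induced gene, went from 1895 ± 54.9 CPM in QS to 10.9 ± 0.99 CPM in ACT, and Ifit3 from 1091 ± 28.3 to 6.68 ± 2.69 CPM. Inflammatory chemokine and cytokine genes fell in 16 and rose in 5 of 22 cases (camera adjusted p = 0.00966), with Ccl5 (-6.83) and Cxcl9 (-6.65) lower and Ptgs2 (5.52), the inducible cyclooxygenase, higher. Of 26 immediate early and dissociation genes 23 fell and 3 rose (median -1.14, camera adjusted p = 1.07e-05, adjusted p = 0.0819 with an estimated correlation), such as Fosb (-3.83) and Hspa1a (-3.48). Glycolysis genes rose in 15 and fell in 2 of 22 cases (median 0.47, camera adjusted p = 0.00512, adjusted p = 0.11 with an estimated correlation), with Pgam1 (1.72) and Eno1 (1.46) among them, and Ldha, which makes lactate from pyruvate, went from 278 ± 10.1 to 641 ± 9.27 CPM. Of 21 tricarboxylic acid cycle genes 19 rose and 1 fell (median 0.40, camera adjusted p = 7.80e-04). All 13 mitochondrially encoded genes fell (median -1.73, camera adjusted p = 1.19e-06, adjusted p = 0.125 with an estimated correlation).

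Genes that mark other liver cells differed between QS and ACT as well. Of 25 hepatocyte markers 24 fell (median -5.03, camera adjusted p = 2.36e-11), for example Alb, the gene of albumin, from 1128 ± 11.7 to 10.6 ± 1.21 CPM. All 22 endothelial markers fell (median -4.94, camera adjusted p = 1.89e-15), as in Dnase1l3, a gene of liver sinusoidal endothelium, from 1744 ± 39.0 to 3.23 ± 0.902 CPM. Macrophage markers were not called as a list (camera adjusted p = 0.276, median 0.63 and mean -0.35): 13 of 22 rose, such as Lyz2 from 513 ± 24.1 to 9350 ± 161 CPM, and 7 fell, such as the Kupffer cell gene Clec4f from 360 ± 9.77 to 3.72 ± 0.634 CPM. Portal fibroblast and smooth muscle markers rose in 7 and fell in 3 of 11 cases (median 3.28, camera adjusted p = 0.0922). Thy1 was 2.36 to 3.57 CPM in the QS libraries and 63.2 to 64.6 CPM in ACT. Cholangiocyte and mesothelial markers rose in 7 and fell in 4 of 13 cases (camera adjusted p = 0.305), with Wt1 at 77.6 to 82.8 CPM in the ACT libraries. Whether such cells added to the rise of contractile and matrix genes was not tested. Over all genes 4592 were called higher and 4289 lower in ACT (limma, adjusted p under 0.05), of which 1965 and 1800 changed at least 2-fold. The libraries of both groups did not overlap in 76.3% of genes, against 10% by chance. Virus, culture and time came together in this comparison, since QS cells received none of them.

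**Figure D2:**
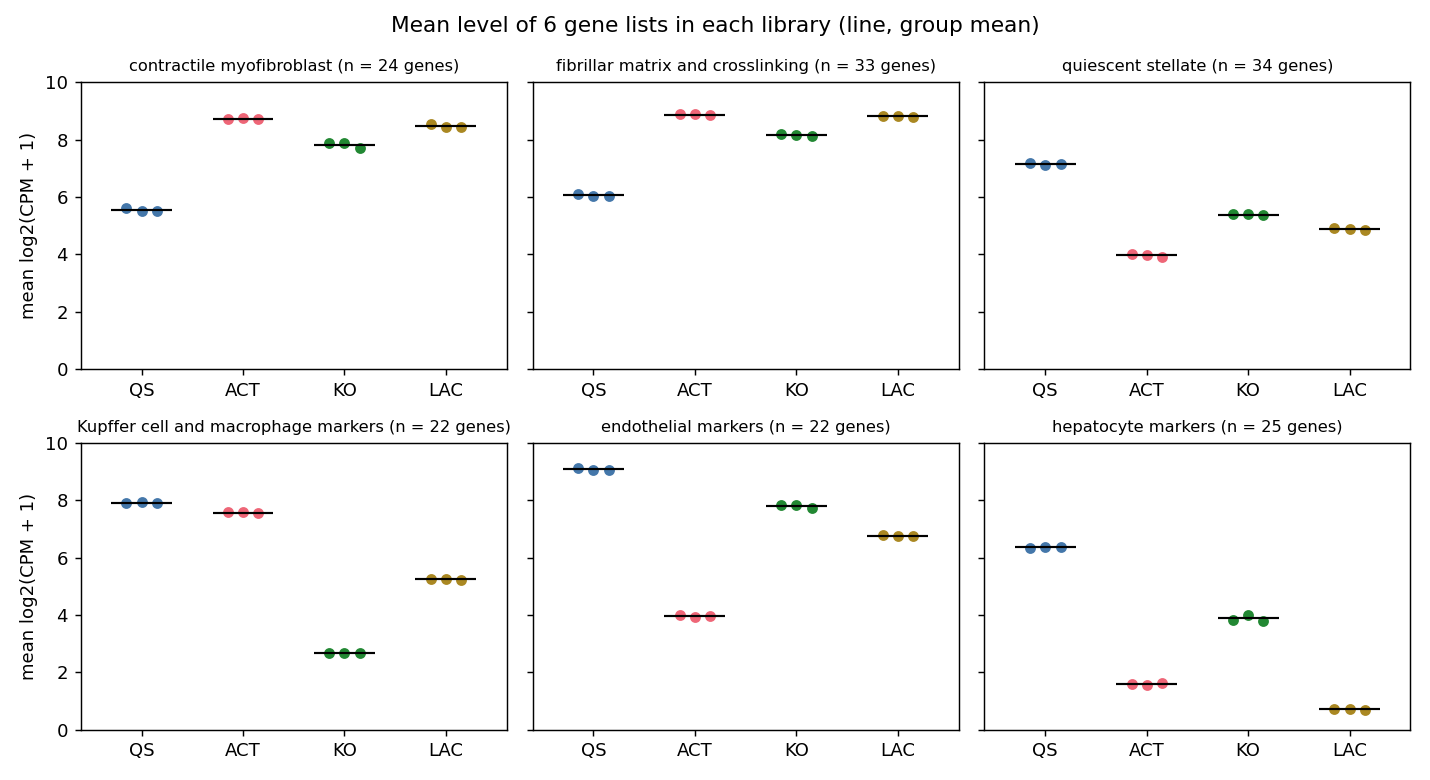
Mean log2(CPM + 1) over the genes of 6 lists (vertical axis) in each of the 12 libraries by group (horizontal axis). Points are libraries and lines are group means. The macrophage list falls from 7.58 in ACT replicate 2 to 2.67 in KO replicate 2 and lies at 5.25 in LAC replicate 2, while the endothelial list goes from 3.94 to 7.84 and 6.75 in the same libraries.

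Deletion of Hk2 was compared with the control virus to ask which genes of the activated state depend on the enzyme. Acta2 and the genes of fibrillar collagens I and III were lower in KO, while those of collagen IV were higher. Acta2 fell from 2656 ± 48.0 to 653 ± 29.1 CPM (log2 fold change -2.02, SE 0.159, adjusted p = 6.37e-08), Col1a1 from 5341 ± 51.3 to 1498 ± 67.9 CPM, Col1a2 from 3305 ± 18.6 to 213 ± 3.53 CPM, Col3a1 from 1572 ± 13.2 to 408 ± 14.1 CPM and Timp1 from 237 ± 4.27 to 101 ± 6.46 CPM. Each stayed above its QS level. Looked at after their values were seen, genes of collagen IV, a component of basement membranes, rose: Col4a1 from 2894 ± 41.5 to 6457 ± 348 CPM (log2 fold change 1.16) and Col4a2 from 1509 ± 17.9 to 3571 ± 232 CPM (1.24). The endothelial list rose in the same comparison (median 4.24), and whether the rise of collagen IV genes came from stellate cells was not tested. Col5a1 (0.02, adjusted p = 0.822) and Col12a1 (-0.16, adjusted p = 0.407) were not called. Of 24 contractile genes 16 fell and 4 rose (median -0.57, camera adjusted p = 3.99e-04, adjusted p = 0.147 with an estimated correlation), with Actg2 (-5.09), Cnn1 (-4.10) and Lmod1 (-2.75) the largest changes. Adjusted over the list alone, 16 fell and 5 rose. Of 33 fibrillar matrix genes 17 fell and 11 rose (median -0.30, camera adjusted p = 0.0127, adjusted p = 0.187 with an estimated correlation), and adjusted over the list alone also 17 and 11. The members that fell most were Spp1 (-5.36), Fn1 (-3.98), Col1a2 (-3.95) and Lox (-2.86), of which Spp1 and Fn1, the genes of osteopontin and fibronectin, are also expressed by macrophages. TGF-beta responsive genes fell in 14 and rose in 7 of 24 cases (camera adjusted p = 0.0102, adjusted p = 0.0819 with an estimated correlation), and Tgfb1 itself was 145 ± 6.68 CPM in ACT and 140 ± 14.5 CPM in KO (adjusted p = 0.535). Matrix turnover genes fell in 11 and rose in 5 of 20 cases (camera adjusted p = 0.0419, adjusted p = 0.135 with an estimated correlation). The quiescent stellate list rose, with 28 of 34 members higher and 4 lower (median 1.67, camera adjusted p = 9.63e-08). Lrat went from 3.09 ± 0.637 to 17.4 ± 2.30 CPM, against 352 CPM in QS, and Rgs5, a pericyte gene, from 8.46 ± 0.323 to 85.8 ± 4.37 CPM. Some members moved over the groups much as markers of other cells did. Rbp4 was 0.595 CPM in ACT, 6.67 CPM in KO and 0.409 CPM in LAC, a course like that of hepatocyte markers. Vipr1, at 0.417, 24.9 and 4.66 CPM, moved like endothelial markers, whereas Rgs5 did not fall from KO to LAC (0.04). Whether the list's rise came from stellate cells alone was not tested.

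Markers of other liver cells differed between KO and ACT as well. Of 22 macrophage markers 21 fell and none rose (median -5.55, camera adjusted p = 2.80e-18). Lyz2, the lysozyme gene of macrophages, fell from 9350 ± 161 to 70.4 ± 1.68 CPM, Itgam from 1037 ± 19.9 to 4.48 ± 1.12 CPM and Adgre1, which encodes F4/80, from 364 ± 4.65 to 2.83 ± 0.719 CPM. Among the 10 named genes with the largest falls were Chil3 (269 ± 2.82 CPM in ACT and listed at 0 in all KO libraries), Arg1 (-7.37), Saa3 (-7.29), Ccl6 (-7.20) and Cybb (-6.82). Endothelial markers rose in 21 of 22 cases, and the remaining member, Vwf, fell (median 4.24, camera adjusted p = 1.08e-15). Clec4g rose from 0.679 ± 0.303 to 114 ± 4.43 CPM and Lyve1 from 8.91 ± 0.87 to 298 ± 9.65 CPM. Hepatocyte markers rose in 23 of 25 cases and fell in 1 (median 2.41, camera adjusted p = 1.36e-07), for example Serpina3k from 0.552 ± 0.156 to 30.5 ± 1.11 CPM. The list of cholangiocyte and mesothelial markers was not called in KO vs ACT (7 of 13 lower, 3 higher, camera adjusted p = 0.0575). Among its members, Wt1 fell, with 79.8 ± 2.71 CPM in ACT and 0.896 ± 0.261 CPM in KO, as did Upk3b with 58.4 ± 2.32 and 0.872 ± 0.395 CPM, while Krt18 (2.11) rose.

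Cell cycle, p53 target and sterol synthesis genes changed in KO. Of 38 cell cycle genes 28 fell and 4 rose (median -0.49, camera adjusted p = 3.71e-04), as in Tk1 (-1.74) and Mki67 (-1.23). Targets of the tumour suppressor p53 rose in 19 and fell in 2 of 25 cases (median 0.65, camera adjusted p = 3.98e-04), with Gdf15 (1.53) and Trp53inp1 (1.29) higher and Sesn1 (-1.93) and Cd80 (-2.00) lower. Sterol synthesis genes fell in 14 and rose in 2 of 21 cases (median -0.37, camera adjusted p = 0.00682), including Dhcr7 (-1.13) and Sqle (-0.96). The lists of the integrated stress response (6 of 25 higher, 13 lower, camera adjusted p = 0.119) and the unfolded protein response (10 of 19 higher, 2 lower, camera adjusted p = 0.192) were not called. Glycolysis genes other than Hk2 went both ways, 7 higher and 5 lower of 22 (median 0.05, mean -0.21, camera adjusted p = 0.867). Slc16a3, a lactate exporter gene, fell from 35.8 ± 0.914 to 15.5 ± 1.2 CPM, and Ldha was 641 ± 9.27 and 588 ± 7.09 CPM (log2 fold change -0.12, adjusted p = 0.00414). Ep300, a histone acetyltransferase gene, was 120 ± 3.33 and 106 ± 9.97 CPM (log2 fold change -0.19, adjusted p = 0.0151). Adjusted over the list alone, 24 hepatocyte markers rose, and 5 cell cycle genes rose and 29 fell; the other lists named for KO had the same counts either way, apart from the contractile list. Over all genes 4354 were called higher and 3179 lower in KO, of which 1108 and 1181 changed at least 2-fold. The libraries did not overlap in 69.2% of genes, against 10% by chance. Every KO library received Cre and every ACT library did not, so the comparison holds any effect of Cre itself and of the cell mixture.

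Many genes that changed with activation changed back in KO. Of 4592 genes called higher in ACT than in QS, 1952 (42.5%) were called lower in KO than in ACT and 1090 higher still. Of 4289 called lower in ACT, 2492 (58.1%) were called higher in KO and 599 lower still. Independent lists of these sizes would share 1208 and 1546 genes, and the odds ratios were 3.77 (Fisher's exact test p = 1.44e-215) and 4.42 (p = 2.11e-304). Genes are not independent replicates, and both fold changes contain the ACT libraries. Across genes the fold changes had a correlation of -0.546 and a covariance of -1.02, where simulated groups without any effect gave -0.501 and -0.0151 (means of 100 simulations). With 1 ACT library held out for the second fold change, the covariance was -1.008 to -1.002 over the 3 choices, and at least 59.4% of the genes higher and 73.5% of the genes lower in activation then had the opposite sign. Endothelial and hepatocyte markers, low in ACT and higher in QS and KO, are among the genes counted here. So are macrophage markers such as Lyz2, high in ACT and lower in QS and KO.

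Lactate was added to Hk2-deleted cells to ask whether it restores what the deletion lowered. The contractile and fibrillar matrix lists were higher in LAC than in KO. Acta2 rose from 653 ± 29.1 to 1434 ± 33.7 CPM (log2 fold change 1.13, SE 0.159, adjusted p = 6.38e-05), Col1a1 from 1498 ± 67.9 to 2691 ± 127 CPM, Col1a2 from 213 ± 3.53 to 691 ± 7.22 CPM, Col3a1 from 408 ± 14.1 to 1086 ± 23.0 CPM and Timp1 from 101 ± 6.46 to 169 ± 1.91 CPM. Of 33 fibrillar matrix genes 22 rose and 6 fell (median 0.42, camera adjusted p = 6.77e-08), with Spp1 (3.06), Col11a1 (2.53), Lox (2.16) and Col8a1 (2.11) the largest. Spp1, also expressed by macrophages, was 5084 CPM in ACT, 123 CPM in KO and 1030 CPM in LAC. Macrophage markers rose from KO to LAC as well (median 3.56), and whether the rise of Spp1 came from stellate cells was not tested. Contractile genes rose in 19 and fell in 2 of 24 cases (median 0.40, camera adjusted p = 3.65e-07, adjusted p = 0.0737 with an estimated correlation), including Actg2 (3.39), Cnn1 (2.98) and Lmod1 (2.25). Counts adjusted over the list alone were the same for both lists. TGF-beta responsive genes rose in 15 and fell in 3 of 24 cases (median 0.41, camera adjusted p = 6.61e-05), such as Ltbp2 (1.57) and Tgfb3 (1.43), while Tgfbi fell (-1.15). Matrix turnover genes rose in 12 and fell in 3 of 20 cases (median 0.41, camera adjusted p = 3.98e-04). Portal fibroblast and smooth muscle markers rose in 7 of 11 cases and fell in none (median 0.84, camera adjusted p = 0.00159), as in Myh11 (2.12). Lrat was not called, at 17.4 ± 2.30 and 14.0 ± 2.00 CPM (log2 fold change -0.29, adjusted p = 0.0882). Pdgfrb, a growth factor receptor gene of stellate cells, rose from 134 ± 4.96 to 159 ± 4.08 CPM (0.25, adjusted p = 2.73e-04). Col4a1 (-0.16) and Col4a2 (-0.28) fell in LAC, as did the endothelial list (median -1.07). The quiescent stellate list fell in 18 and rose in 10 of 34 cases (median -0.33, camera adjusted p = 0.025, adjusted p = 0.0905 with an estimated correlation). Among those that fell were Rbp4 (-2.44) and Vipr1 (-2.20), whose course resembled that of markers of other cells.

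Lactate metabolism genes moved singly. Slc16a3 rose from 15.5 ± 1.2 to 46.3 ± 0.562 CPM (log2 fold change 1.53, adjusted p = 6.02e-09), while Slc16a1, which encodes another lactate carrier, fell from 54.0 ± 1.86 to 35.1 ± 2.85 CPM (-0.61). The list of lactate transport and metabolism was not called (6 of 16 higher, 4 lower, median -0.04, mean 0.20, camera adjusted p = 0.586). Glycolysis genes rose in 11 and fell in 1 of 22 cases (median 0.24, camera adjusted p = 0.00151, adjusted p = 0.0819 with an estimated correlation), with Hk3 (3.43) and Tpi1 (0.66) among them. Hk3 is the hexokinase gene of myeloid cells, and macrophage markers rose in the same comparison (median 3.56). Whether the rise of Hk3 came from macrophages was not tested. Ldha went from 588 ± 7.09 to 754 ± 12.9 CPM (0.36, adjusted p = 7.51e-07), and Ep300 was 106 ± 9.97 and 117 ± 2.82 CPM (adjusted p = 0.0701).

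Markers of macrophages, endothelial cells and hepatocytes, which differed between KO and ACT, differed between LAC and KO in the reverse direction. So did the portal fibroblast and smooth muscle list given above and the lymphocyte and neutrophil list (3 of 4 higher, 1 lower, camera adjusted p = 0.0157, adjusted p = 0.0795 with an estimated correlation), both lower in KO than in ACT with the preset correlation only (camera adjusted p = 0.0431 and 0.0257, adjusted p = 0.135 and 0.0905 with an estimated correlation). Cholangiocyte and mesothelial markers rose in 6 of 13 cases and fell in none (median 0.27, camera adjusted p = 0.0264, adjusted p = 0.0833 with an estimated correlation). Macrophage markers rose in 16 and fell in 3 of 22 cases (median 3.56, camera adjusted p = 2.07e-13), as in Lyz2 from 70.4 ± 1.68 to 2240 ± 24.5 CPM and Itgam from 4.48 ± 1.12 to 236 ± 5.60 CPM. Of members looked at after their values were seen, Marco, a scavenger receptor gene of Kupffer cells, was 1.39 CPM in KO and 2.33 CPM in LAC, against 194 CPM in ACT. Endothelial markers fell in 21 of 22 cases and Vwf rose (median -1.07, camera adjusted p = 4.30e-17), for example Gpr182 from 100.4 ± 7.11 to 37.2 ± 1.66 CPM. Hepatocyte markers fell in 23 and rose in 2 of 25 cases (median -3.45, camera adjusted p = 4.97e-18). Alb was 157 ± 3.58 CPM in KO and 0.601 ± 0.254 CPM in LAC, and Serpina1b 20.6 ± 1.51 CPM in KO and listed at 0 in all LAC libraries. Adjusted over the list alone, the members higher and lower were 16 and 4 for the TGF-beta responsive list, 13 and 3 for matrix turnover, 8 and 0 for portal fibroblast markers, 11 and 20 for the quiescent stellate list, 6 and 5 for lactate metabolism and 12 and 1 for glycolysis, and the same as over all genes for the other lists named for this comparison. Over all genes 2415 were called higher and 2542 lower in LAC. Of these 618 and 264 changed at least 2-fold. The libraries did not overlap in 52.2% of genes, against 10% by chance.

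Many differences between KO and ACT were smaller in LAC. Of 3179 genes called lower in KO than in ACT, 1814 (57.1%) were called higher in LAC than in KO and 66 lower still. Of 4354 called higher in KO, 2089 (48.0%) were called lower in LAC and 260 higher still. Independent lists would share 635 and 916 genes. The odds ratios were 18.3 and 14.8, with Fisher's exact test p below the smallest number the computation can hold. Across genes the correlation of both fold changes was -0.799 and the covariance -0.633, against -0.503 and -0.0152 in 100 simulations without any effect. With 1 KO library held out, the covariance was -0.620 to -0.607 and the correlation -0.755 to -0.727. Over the 2289 genes called and at least 2-fold apart between KO and ACT, LAC lay a median of 0.391 of the log2 distance from KO to ACT (quartiles 0.228 to 0.569). These genes include 20 macrophage, 22 endothelial and 21 hepatocyte markers. By list, this median share over the genes at least 2-fold apart was 67% for 7 contractile genes, 44% for 14 fibrillar matrix genes and 64% for macrophage markers. It was 27% for endothelial markers, 22% for quiescent stellate genes and 116% for hepatocyte markers. The last value rests on low levels, as 20 of the 25 hepatocyte markers had a LAC mean under the level of 3 reads. Of the 14 fibrillar matrix genes 10 were lower and 4 higher in KO. Among those higher, Tnc (0.35) and Thbs2 (1.27) moved further from ACT in LAC, while Col4a1 (-0.16) and Col4a2 (-0.28) moved back. On the linear scale, the 17 contractile and matrix genes at least 2-fold lower in KO reached a median of 39.0% of the way to ACT. In all, 1258 genes rose with activation, fell in KO and rose in LAC, of which 345 did so by at least 2-fold at each step. The mirror course was followed by 1447 genes, of which 219 did so by at least 2-fold at each step. Macrophage markers such as Lyz2 and Itgam took the first course. Alb and Gpr182, markers of hepatocytes and endothelial cells, took the mirror course. The counts thus include markers of other cells, and no number expected by chance was computed for them.

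**Figure D3:**
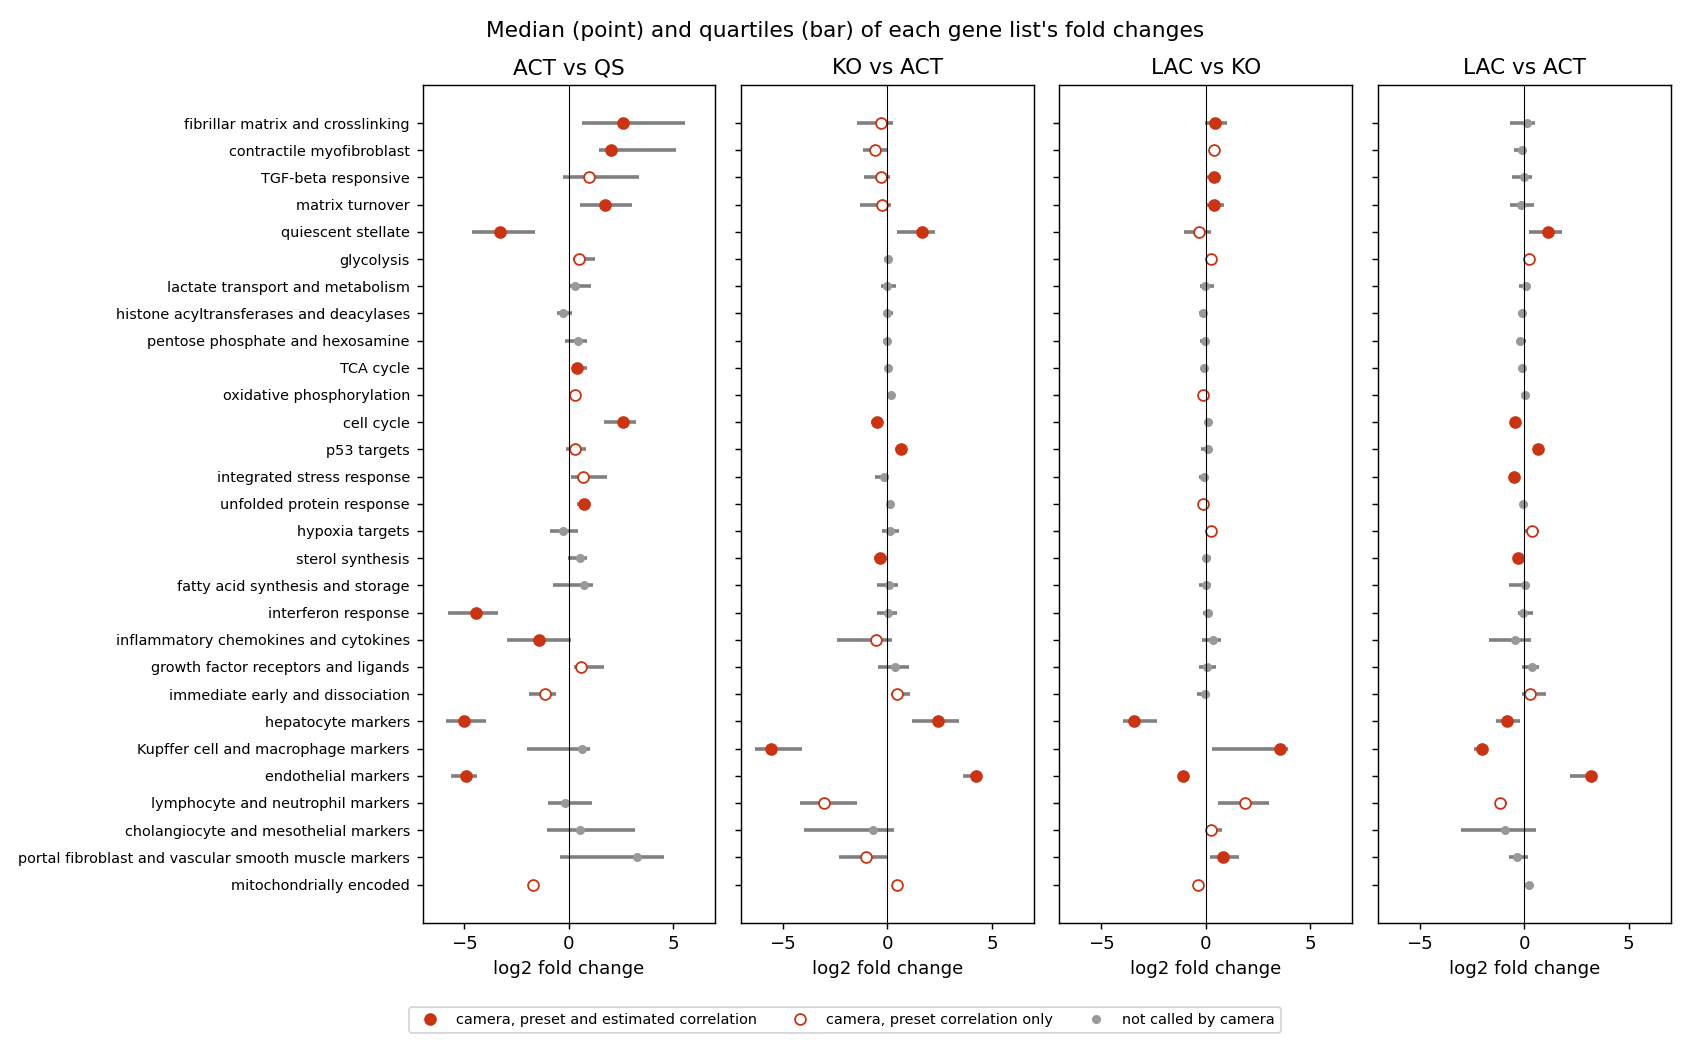
Log2 fold changes (horizontal axis) of 29 gene lists (vertical axis) in the 4 comparisons. Points are medians over a list's genes and bars the quartiles. Filled red points passed camera with the preset and with an estimated correlation, open red points with the preset correlation only, and grey points neither. The macrophage list has its median at -5.55 in KO vs ACT and at 3.56 in LAC vs KO.

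Lactate-treated cells were set against activated cells to describe what differed between them. Acta2 was still lower in LAC (1434 ± 33.7 against 2656 ± 48.0 CPM, log2 fold change -0.89, adjusted p = 3.35e-04), as were Col1a1 (-0.99), Col1a2 (-2.26) and Col3a1 (-0.53). The contractile list (13 of 24 lower, 5 higher, camera adjusted p = 0.0836) and the fibrillar matrix list (11 of 33 lower, 15 higher, median 0.13, mean -0.05, camera adjusted p = 0.959) were not called. Thbs2, a matrix protein gene, stood at 149 ± 4.73 CPM in LAC and 22.6 ± 1.62 CPM in ACT, and the matrix protease gene Mmp3 at 235 ± 9.75 and 34.4 ± 2.31 CPM. With 61.3 and 141 CPM in KO, both genes moved further from ACT in LAC. Quiescent stellate genes were higher in 25 and lower in 6 of 34 cases (median 1.16, camera adjusted p = 3.04e-06), led by Rgs5 (3.23) and Prelp (3.08). Targets of p53 were higher in 21 and lower in 2 of 25 cases (median 0.66, camera adjusted p = 1.08e-06), with Perp (1.68) and Trp53inp1 (1.39) higher and Sesn1 (-1.61) lower. Cell cycle genes were lower in 23 and higher in 3 of 38 cases (median -0.43, camera adjusted p = 4.24e-05). Integrated stress response genes were lower in 17 and higher in 4 of 25 cases (median -0.47, camera adjusted p = 6.04e-04), as in Atf3 (-1.12) and Aldh1l2 (-1.01). That list was not called in KO vs ACT (camera adjusted p = 0.119). Sterol synthesis genes were lower in 13 and higher in 1 of 21 cases (median -0.28, camera adjusted p = 0.00267). Macrophage markers were lower in all 22 cases (median -2.04, camera adjusted p = 3.25e-19), endothelial markers higher in 21 of 22 (median 3.18, camera adjusted p = 6.92e-19) and hepatocyte markers lower in 16 and higher in 1 of 25 (median -0.83, camera adjusted p = 1.68e-05). The genes with the largest rises included the protease inhibitor gene A2m (5.44), the endothelial gene Lyve1 (4.20) and Nefl (3.96), which encodes a neurofilament protein. Adjusted over the list alone, 24 cell cycle and 18 integrated stress response genes were lower, and the other lists named here had the same counts. Over all genes 3362 were called higher and 2618 lower in LAC than in ACT, of which 781 and 743 changed at least 2-fold.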

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

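The test against a minimum change of 1.2-fold and the fit without marker genes of other cells and mitochondrially encoded genes were chosen after seeing the data. No gene named by the rule and called in the main fit reversed its direction under the alternatives run, and no called list did by its median. Sign changes of genes and lists not called were not counted. Settings that reuse the main fold changes, such as other thresholds, fry and the estimated correlation, could not show a reversal. Among all genes called both ways, quantile normalization turned the sign of 2 of 8317 in ACT vs QS, 2 of 7232 in KO vs ACT, 1 of 4776 in LAC vs KO and 1 of 5671 in LAC vs ACT. Limma's fry gave the direction opposite to camera in 7 of 116 list tests, none of them called by camera. Of these, fry called 2, both in LAC vs ACT: fibrillar matrix as lower (fry adjusted p = 0.00264) and interferon response as higher (fry adjusted p = 0.00114). The counts of genes called stayed within 1.5 times under pseudocounts of 0.1, 0.5 and 5, a filter of 5 CPM, rescaled totals, quantile normalization, median centring, fewer groups in the fit, robust or untrended moderation, weights per library, each library left out, and without the marker and mitochondrially encoded genes.

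A minimum of 2-fold beside the adjusted p lowered the counts by construction, to 1965 higher and 1800 lower in ACT vs QS, 1108 and 1181 in KO vs ACT, 781 and 743 in LAC vs ACT and 618 and 264 in LAC vs KO. Hk2 in LAC vs KO (0.64) lies under that minimum. Tested against a change of 1.2-fold, 2496 genes were higher and 2049 lower in KO vs ACT, 1750 and 1360 in LAC vs ACT and 1066 and 703 in LAC vs KO. With an adjusted p under 0.01, 1681 genes were lower in LAC vs KO. The balance of genes higher and lower turned in LAC vs KO, where genes higher were 48.7% of those called without a minimum, 70.1% with the 2-fold minimum, 60.3% in the 1.2-fold test, 51.5% with an adjusted p under 0.01 and 50.6% without KO replicate 1. It turned in KO vs ACT as well, from 57.8% without a minimum to 48.4% with the 2-fold minimum. Among 116 list tests, an estimated correlation ended 30 of 63 calls, and fry added 42.

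The numbers of the replicates do not pair the libraries: the 18 correlations of the deviations of libraries with the same number ran from -0.042 to 0.086, and a library correlated best with its own number in 6 of 18 cases. With the replicate number as a block, 4594 genes were higher and 4299 lower in ACT vs QS, 4365 and 3177 in KO vs ACT, 2397 and 2538 in LAC vs KO and 3366 and 2586 in LAC vs ACT. Each number occurs once in each group, so the block leaves all fold changes and their correlations (-0.546 and -0.799) as they were by design. Leaving out the filter on low values was not run, since it removes no gene, and the test on counts was not run, since whole reads could not be recovered. At the real depths and 3 libraries per group, 37.3% to 41.8% of genes changed 1.2-fold were called in simulated data. That holds for genes above a minimum level and for the spread assumed there. Whether depth or the number of libraries sets this share was not tested.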

Other observations

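The tests of explanations in this part were chosen after the results were seen, except those on other splits of the samples. Beyond the genes described above, lipid and growth factor genes differed between the cultured groups in single members. Lpl, the gene of lipoprotein lipase, was 2307 ± 58.9 CPM in ACT, 180 ± 9.17 CPM in KO and 693 ± 12.3 CPM in LAC (SD, n = 3), and Fabp5, a fatty acid carrier gene, 382 ± 11.8, 66.6 ± 4.84 and 196 ± 11.9 CPM. The list of fatty acid synthesis and storage was not called in KO vs ACT (7 of 19 higher, 8 lower, median 0.07, mean -0.11, camera adjusted p = 0.305). Igf1, a growth factor gene, was 336 ± 9.61 CPM in ACT, 12.5 ± 2.02 CPM in KO and 105 ± 3.48 CPM in LAC, and its list was not called in KO vs ACT (12 of 21 higher, 6 lower, camera adjusted p = 0.385). Macrophage markers moved with these genes (median -5.55 in KO vs ACT and 3.56 in LAC vs KO). Il7r fell from 127 ± 5.98 CPM in ACT to 2.65 ± 0.484 CPM in KO and was 52.1 ± 1.95 CPM in LAC. In its list of lymphocyte and neutrophil markers 3 of 4 measured members fell and 1 rose in KO vs ACT (camera adjusted p = 0.0257, adjusted p = 0.0905 with an estimated correlation). Portal fibroblast and smooth muscle markers fell in 8 and rose in 3 of 11 cases (camera adjusted p = 0.0431, adjusted p = 0.135 with an estimated correlation), with Thy1 at 64.1 ± 0.771 CPM in ACT and 3.41 ± 0.577 CPM in KO.

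Genes of histone modification and energy metabolism moved little as lists in KO vs ACT. Histone acyltransferase and deacylase genes were higher in 4 and lower in 7 of 28 cases (camera adjusted p = 0.792), and Hdac9 went from 10.8 ± 0.792 to 0.43 ± 0.189 CPM (SD, n = 3). Pentose phosphate and hexosamine genes were higher in 4 and lower in 3 of 15 cases (median -0.02, mean 0.03, camera adjusted p = 0.782). Oxidative phosphorylation genes were higher in 18 and lower in 1 of 40 cases (camera adjusted p = 0.106). Adjusted over the list alone, these were 4 and 6, 3 and 3, and 17 and 0. Mitochondrially encoded genes rose in 11 of 13 cases in KO vs ACT (camera adjusted p = 0.00268, adjusted p = 0.291 with an estimated correlation). Unfolded protein response genes rose in 16 and fell in 2 of 19 cases in ACT vs QS (median 0.71, camera adjusted p = 3.51e-04), such as Calr from 502 ± 24.9 to 1201 ± 7.55 CPM. Hypoxia targets were higher in 10 and lower in 1 of 18 cases in LAC vs ACT (median 0.36, camera adjusted p = 0.0117, adjusted p = 0.0819 with an estimated correlation), led by Adm and Ndrg1 (log2 fold changes 1.80 and 1.69).

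Macrophage genes were lower in KO than in ACT and between both in LAC. Dilution of a common cell mixture would lower all lists alike, but the median log2 fold change of the macrophage list lay -4.98 from that of the contractile list. Loss of macrophages alone would leave the other cell types in proportion, but the endothelial list lay 4.53 above the fibrillar matrix list. A smaller share of otherwise similar macrophages in LAC than in ACT stays open for most of the list. Of its genes 77.3% (17 of 22) lay within 2-fold of the list's median ratio of 0.220. Those outside were Vsig4, Cd5l, Marco, Timd4 and Cd163. Marco was 191.5 to 196 CPM in the ACT libraries and 2.03 to 2.74 CPM in LAC. Cd5l was 216.8 to 227.7 and 6.53 to 7.99 CPM, and Vsig4 45.9 to 54.9 and 2.93 to 4.39 CPM. Such larger falls argue against otherwise similar macrophages for these genes. An effect of Hk2 and lactate on macrophages themselves may apply as well and was not tested.

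Contractile and matrix genes were higher in LAC than in KO. ACT RNA mixed into the LAC libraries would carry all genes the same part of the way, but Hk2 reached 4.3% of the way from KO to ACT (upper bound 5.3%), while the 17 contractile and matrix genes at least 2-fold lower in KO reached a median of 39.0% (quartiles 29.0% to 58.3%). This test replaced an earlier one whose result had been seen: genes beyond both ACT and KO in LAC were to exceed 5% and made up 1.7% (204 of 12081), which did not count against mixing. A larger share of similar stellate cells would raise their genes alike, but 6 stellate genes spanned 1.99 on the log2 scale, from Lrat to Col1a2. Separate cultures with other cell mixtures, as the hepatocyte list's median of -3.45 in LAC vs KO may reflect, cannot be told apart from lactate because the labels do not say whether KO and LAC cells came from the same preparation.

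Hepatocyte genes were higher in KO than in ACT and LAC. Carry-over of QS RNA would bring macrophage RNA at the same share, but the upper quartile of the KO to QS ratio of the macrophage list was 0.043, against 0.151 for the median of the hepatocyte list. This test also replaced an earlier one after its result was seen: of 2335 genes with at least 100 CPM in QS, 123 (5.3%) lay below the share that carry-over needs, barely past the 5% set for it. A rise by Hk2 deletion that lactate only undoes would leave these genes in LAC at their ACT level or above. The list's median in LAC vs ACT was -0.83, with 16 of 25 genes lower and 1 higher. Alb was 9.19 to 11.4 CPM in the ACT libraries and 0.338 to 0.844 CPM in LAC. The 16 lower genes lay below what an undoing that stops at the ACT level would give. A fall with lactate that went past that level is not excluded, so the test cannot decide. For the other genes an undoing stays open as well, as 8 were not called. Of all 25, 20 had a LAC mean and 8 an ACT mean under the level of 3 reads (0.338 CPM at most). The limit on such low levels was added to this test after its result was seen. Hepatocytes or their RNA in KO may account for the level, since 92.0% of the list (23 of 25 genes, all but Hpx and Ass1) lay within 1.5-fold of its median ratio.

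Other splits of the 6 samples of each comparison were fitted with limma. Only 1 of the 10 splits, the real one, gave as many genes in each comparison: 8837 genes in ACT vs QS, 7747 in KO vs ACT, 4905 in LAC vs KO and 6743 in LAC vs ACT, where the highest other split gave 0, and at an unadjusted p under 0.05 gave 41, 73, 245 and 120. With 10 splits the share cannot fall under 0.05. Every other split puts libraries of both real groups on each side. The difference between the real groups then enters the spread, which makes calls few by design. The contrast with the real split therefore lends no further support.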
